A study of Mus musculus with 2 samples.

How the data were processed

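DNase-seq marks open chromatin: nuclei are treated with the enzyme DNase I, which cleaves accessible DNA, and the released fragments are sequenced. The libraries were made from whole adrenal glands of male B6CASTF1/J mice, the first-generation cross of the C57BL/6J and CAST/EiJ strains, aged 8 to 10 months per the labels. The labels give 1 group with 2 biological replicates. Each replicate is a pool of 6 adrenal gland biosamples and 1 library. The labels give both pools the same donor identifier, and the number of animals behind the biosamples is not given in the sources used here. There is no treated or control group, so the work describes each pool, how far the pools repeat each other, and how peaks lie relative to genes and sequence motifs.

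For each pool the authors deposited 2 peak lists, a list of footprints and a table of false discovery rates, all on the mouse assembly mm10 (GRCm38) per the labels and the readme texts. Per these texts, peaks and the table were derived from the filtered alignments of the same library, so peaks were called per pool. The aligner, the peak caller, the footprint caller, their versions and their thresholds are not given in the sources used here. Each peak carries the authors' signal, which is 0 or more, and the deposited columns for a score, a p-value, a q-value and a summit hold 1 constant each, so the signal was the value used to rank peaks and the midpoint stood in for the summit. Every deposited signal value in a list was a whole multiple of 1 step, 0.00743 in replicate 1 and 0.00799 in replicate 2, within a tolerance of 0.05 of a step for 100% of values. If the signal is scaled per 1000000 cleavages, these steps correspond to totals of 134.6 and 125.1 times that number, but the sources do not state the scaling and the depth of the libraries is therefore inferred, not known. The median peak had a signal of 94 and 91 steps. The deposited table gives each interval's false discovery rate (FDR), a p-value adjusted for multiple tests, for the rate of cleavage. It lists only intervals with an FDR under 0.05 and holds no counts. The footprint value was 0.01 for every footprint in both pools, so footprints could not be ranked.

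Both peak lists had the same format, and the longer one was the main list by a rule written before the data were examined. All peaks of the main list held intervals with an FDR under 0.05, and all peaks of the other list held an interval with an FDR of 0.001 or lower. The gene lists, motifs, tests, rule for named genes and alternatives were fixed before the data were examined, except where the text says that a choice followed the data. Peaks were compared by overlap of at least 1 bp, with 100 random placements on the same chromosome outside assembly gaps as the reference. Regions shared by both pools are merged peaks that hold a peak of each. Genes came from the basic set of GENCODE M21 on the 21 chromosomes, with 77161 transcription start sites (TSSs). The tests used 21911 protein-coding genes, 1 record per symbol. A promoter peak overlaps the interval within 1 kb of a TSS of the gene. For the location of peaks, the midpoint was put in the promoter class within 1 kb of any annotated TSS, else in an exon, an intron or between genes. A distal region lies over 1 kb from every TSS and was counted for each gene with a TSS within 50 kb, so 1 region can count for several genes and is not assigned to any.

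The 22 gene lists held 272 distinct genes, of which 271 matched by symbol. They covered the cortex (steroidogenesis, zona glomerulosa and capsule, cholesterol synthesis), the medulla (chromaffin cells, Schwann and sustentacular cells), other cells a whole gland could hold (endothelium, macrophages, lymphocytes, fibroblasts, smooth muscle and pericytes, adipocytes, erythroid cells), other organs (gonadal steroidogenesis, hepatocytes, kidney tubules and podocytes, skeletal muscle, forebrain neurons, spermatogenesis) and gene programs (housekeeping, glucocorticoid response, immediate early, circadian clock). Members with a promoter peak in both pools were compared with the other genes by Fisher's exact test, two-sided. The median number of shared distal regions per member was compared with 10000 random lists of the same size, matched in 10 classes of gene density within 100 kb and 10 of gene length, as a two-sided permutation test. The p-values were adjusted over the 22 lists by the Benjamini-Hochberg method. Genes are not independent replicates, and these tests say nothing about spread between animals.

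Consensus sequences of 28 motifs were matched on both strands within 75 bp of the midpoint of distal peaks. The controls were windows of the same 151 bp placed 1 kb away on either side and touching no peak. A motif was called where, in both pools, Fisher's exact test had an adjusted p under 0.05, the ratio of the shares was at least 1.5, and it was at least 1.5 times the ratio of the reversed, not complemented, consensus. Footprints were extended by 10 bp on each side and compared with windows of the same size in the same peak that touched no footprint. The reference sequence was GRCm38, whose C57BL/6J alleles differ from the CAST/EiJ alleles at many sites, so a motif present only on the CAST/EiJ copy was not searched.

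The rule for named genes took, from the lists steroidogenesis, zona glomerulosa and capsule, cholesterol synthesis and chromaffin cells, the 5 members with the most shared distal regions and up to 5 members with no promoter peak in both pools. From every other list it took the 2 members with the most. It also took the 10 genes with the most in the genome, the nearest TSS of the 10 shared peaks with the best mean rank of signal, and that of the 5 best-ranked peaks found in 1 pool alone. A few further members are named where a count calls for it, and were chosen after their values were seen. Some genes that the rule took are not reported here, though they stay in the list tests.

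The signal ratio of the pools in shared regions was computed after the data were seen. It is the log2 ratio of replicate 2 to replicate 1, minus its median over all shared regions, which removes any constant factor between the libraries. For 23 of the 28 motifs, those with at least 50 shared distal regions, the median was set beside 1000 random sets of regions matched on 10 classes of signal and 10 of GC content, and a 95% interval came from 1000 bootstrap draws over regions. For gene lists with at least 5 members that had a value, medians were ranked among 10000 random lists matched on signal. With 1 library per pool these ratios compare 2 libraries, and no p-value was computed.

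The alternatives were the other peak list, the 50% of peaks with the most signal, the same number of best peaks in both pools, each pool alone, an overlap of 50% of both intervals, promoters within 500 bp or 2 kb, distal regions within 20 or 100 kb, lists not matched, means in place of medians, motif windows of 150 bp on each side, control windows matched on GC content to 5 percentage points, all peaks in place of distal ones, and footprints with no bases added. The procedures were tested on simulated data. Overlaps of 12000 simulated intervals differed from a direct count in 0 cases. Of 20 simulated lists of 20 genes with a promoter peak in 95% of members, 19 were called, and 0 of 20 unchanged lists were. Of 20 lists with distal counts multiplied by 2 and raised by 2 more, 20 were called, as was 1 of 20 unchanged lists. Of 5 motifs planted in 4% of 20000 windows, 4 were called, and the share rose by 3.78 to 3.97 points. The motif not called was REST, because its reversed consensus had no match in the controls, and 0 of 23 other motifs were called. Both sets were a random split of the same windows, so this check could not show false calls from base composition. Real distal peaks had 50.4% and 49.8% GC in replicates 1 and 2, against 44.6% and 44.4% in their flanks. The planted share was also above that of rarer called motifs, such as GRE in 1.12% and 0.724% of distal peaks. A planted shift of -0.40 in the signal ratio of 700 regions was recovered as -0.40. This checked the centring alone, and not the motif matching or the random sets of regions. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.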

Results

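Open chromatin of the adrenal gland was mapped in 2 pools of 6 biosamples each from adult male mice. The deposited main list held 117371 DNase I peaks in replicate 1 and 146307 in replicate 2 (131839 ± 20461, mean ± SD, n = 2). Peaks had a median width of 200 bp in both pools and covered 24.0 and 30.3 Mb (27.2 ± 4.43, SD, n = 2). The authors' signal had a median of 0.699 in replicate 1 and 0.727 in replicate 2. A second, shorter list held 71596 and 93862 peaks. Cleavage passed an FDR of 0.05 over 37.0 Mb in replicate 1 and 49.4 Mb in replicate 2, and an FDR of 0.001 over 21.7 and 29.9 Mb. Main peaks held 63.8% and 60.3% of the bases listed at the first of these levels. Each pool was 1 library, so differences between the pools are given as values without a test.

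The strongest region of both pools lay on chromosome 17 at 39846781 to 39846920 (mm10, as are all positions), inside a gene annotated as ribosomal RNA, with a signal of 51.6 in replicate 1 and 75.8 in replicate 2. Second by mean rank was an intergenic region on chromosome 3 at 5860361 to 5860530, with 27.4 and 39.6. The next lay on chromosome 17 at 6429981 to 6430180, 31 bp from the TSS of Dynlt1b, a dynein light chain gene, with 27.6 and 35.9. On chromosome 9, an exon of Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, held a peak at 123461881 to 123462160 with 26.4 and 39.3. The promoter of Hjurp, whose product loads the centromeric histone, had 21.6 and 29.9, and that of Dnpep, an aminopeptidase gene, 18.8 and 22.8. Peaks near Gatad2a, a subunit gene of the NuRD complex, had 18.6 and 20.2, and those near Kpna1, an importin gene, 18.0 and 23.5. An exon of Cers5, a ceramide synthase gene, had 27.6 and 22.5, and was the only one of these 10 regions with less signal in replicate 2. The remaining one was intergenic on chromosome 6, 21564 bp from a TSS of Igf2bp3, with 23.0 and 30.5. No regions of repeated or poorly mapped sequence were removed here. Whether the high signal of these 10 regions reflects open chromatin was therefore not tested.

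Of the peaks of replicate 1, 99299 (84.6%) overlapped a peak of replicate 2, and 99295 (67.9%) of the peaks of replicate 2 overlapped one of replicate 1. Peaks placed at random were shared in 2.46% and 1.97% of cases, so the observed shares were 34.4 times higher in both directions. Sharing followed the signal. Among the 10% of peaks with the most signal, 99.8% and 99.6% were shared, against 48.3% and 17.2% of the 10% with the least. The merged peaks gave 96584 shared regions over 26.0 Mb. Across these regions the signal of the pools had a Spearman correlation of 0.943 and, as log2, a Pearson correlation of 0.956, but regions are not independent replicates. The median log2 ratio of replicate 2 to replicate 1 was 0.35 (SD over regions 0.37), and 98.7% of regions lay within 2-fold of that median.

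**Figure D1:**
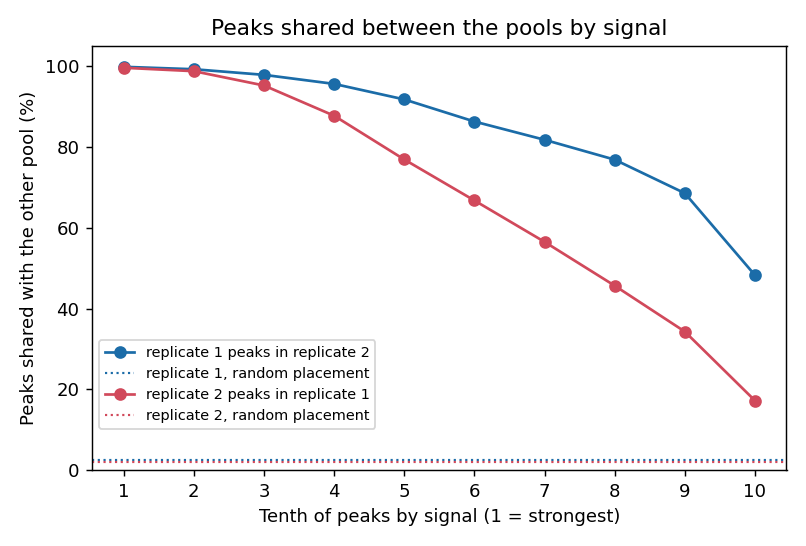
Percent of each pool's peaks that overlap a peak of the other pool (vertical axis) in 10 classes of the authors' signal, strongest first (horizontal axis), with dotted lines for random placement. Replicate 1 (blue) goes from 99.8% to 48.3% and replicate 2 (red) from 99.6% to 17.2%, while random placement gives 2.46% and 1.97%.

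Promoters, taken as 1 kb on either side of a TSS, held 23.8% ± 1.65 of peaks (SD, n = 2) against 4.50% of randomly placed peaks, a 5.29-fold excess. Exons held 4.38% ± 0.0106 (random 3.09%), introns 40.5% ± 0.919 (random 42.2%) and the space between genes 31.3% ± 0.744 (random 50.2%). Peaks shared by the pools lay in promoters in 25.6% (replicate 1) and 25.7% (replicate 2) of cases. This share was 21.5% for the 18072 peaks of replicate 1 alone and 16.3% for the 47012 of replicate 2 alone.

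By chromosome, the X chromosome had 19.8 peaks per Mb in replicate 1 and 25.7 in replicate 2, against 47.6 and 59.3 on the autosomes, a ratio of 0.417 and 0.433. Chromosome 11 was the densest autosome (70.3 and 84.6 per Mb) and chromosome 3 the sparsest (37.9 and 47.5). The Y chromosome had 0.953 and 0.987 peaks per Mb. With only the 50% of peaks with the most signal, an alternative added after the data were seen, the mean X to autosome ratio was 0.236.

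Promoters of most steroidogenesis genes were open in the gland, though a comparison with all other genes does not show that this is particular to it. A promoter peak was present in both pools at 18 of 20 steroidogenesis genes, 90%, against 61.9% of the other protein-coding genes (adjusted p = 0.0212, Fisher's exact test). Star, whose product carries cholesterol into mitochondria, had a promoter signal of 5.44 in replicate 1 and 6.52 in replicate 2. Cyp11a1, which encodes the side-chain cleavage enzyme that makes pregnenolone, had 4.45 and 5.20. Fdxr, the gene of the reductase that feeds electrons to that enzyme, had 12.6 and 13.8, and Tspo, a gene of the outer mitochondrial membrane, had 2.94 and 3.38. The 2 members without a promoter peak in both pools were Hsd3b1, which had none in either, and Nr0b1, a repressor gene on the X chromosome, which had one of signal 0.328 in replicate 2 alone. All 18 cholesterol synthesis genes had a promoter peak in both pools (adjusted p = 0.00509, Fisher's exact test). Their signals included 12.6 and 14.5 at Dhcr7, the gene of the last reductase of the pathway, 11.7 and 13.9 at Fdft1, the squalene synthase gene, 8.12 and 9.65 at Fdps, and 3.85 and 5.20 at Sc5d.

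In the outer cortex, the zona glomerulosa and capsule list did not pass the test (adjusted p = 0.411, Fisher's exact test). Of its 17 genes, 13 (76.5%, against 61.9% of the other genes) had a promoter peak in both pools. Members with one included Dab2 (2.76 and 4.10), a marker of glomerulosa cells, Axin2 (3.71 and 5.15) and Znrf3 (4.49 and 5.63), both feedback genes of Wnt signalling, and the potassium channel gene Kcnk3 (2.01 and 2.17). Cyp11b2, the aldosterone synthase gene, and Kcnk9 had none in either pool. Nr2f2 and Tcf21, a marker of capsule cells, had one in replicate 2 alone, with signals of 1.49 and 0.288.

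In the medulla, 21 of 25 chromaffin cell genes had a promoter peak in both pools (adjusted p = 0.0390, Fisher's exact test). Th, the gene of the rate-limiting enzyme of catecholamine synthesis, had signals of 1.65 and 2.23, and Dbh, which encodes the enzyme that makes noradrenaline, 1.72 and 2.37. Values were 0.706 and 1.22 at Chga, the chromogranin A gene, 0.699 and 1.10 at Hand1 and 0.899 and 1.54 at Snap25. Members with a promoter peak in replicate 2 alone included Pnmt (0.695), the gene of the enzyme that makes adrenaline, Resp18 (0.480) and Ret (0.288). The call on this list did not hold with the shorter peak list (adjusted p = 0.401), with the 50% of peaks with the most signal (0.266), with the same number of peaks in both pools (0.0931), with promoters of 500 bp (0.0665) or in replicate 1 alone (0.0614), all by Fisher's exact test. In replicate 2 alone all 25 members had a promoter peak (adjusted p = 0.00061, Fisher's exact test).

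Of the lists for other cell types in the gland, lymphocyte genes alone passed the test, and lists this short can miss a difference. Counts in both pools were 12 of 14 for endothelium (adjusted p = 0.141), 5 of 9 for Schwann and sustentacular cells (0.739), 5 of 9 for smooth muscle and pericytes (0.739), 6 of 12 for macrophages (0.478), 3 of 10 for fibroblasts (0.0788), 4 of 10 for adipocytes (0.268) and 3 of 7 for erythroid cells (0.508), none of which passed Fisher's exact test. Lymphocyte genes had 1 of 11, Lck, a T-cell kinase gene, which was lower than the other genes (adjusted p = 0.00509, Fisher's exact test). Lck itself was lost with the shorter peak list and with promoters of 500 bp, where the count was 0 of 11. With the shorter peak list 0 of 12 macrophage genes and 2 of 10 fibroblast genes had a promoter peak, and both lists were then lower (adjusted p = 0.000321 and 0.0387, Fisher's exact test). Macrophage genes were also lower with the 50% of peaks with the most signal (0.0058, exact test). With the same number of peaks in both pools macrophage and fibroblast genes were both lower (0.0275 each, exact test), and fibroblast genes were also lower with promoters of 500 bp (0.0311, exact test). Kdr, the main VEGF receptor gene of endothelium, had promoter signals of 0.884 and 1.07, and Erg 0.282 and 0.520. Sox10, Fcer1g, Cd4, Postn, Cnn1 and Cfd had no promoter peak in either pool, and Spi1, a macrophage regulator gene, had one in replicate 1 alone (0.669). Signals were 0.320 and 0.320 at the collagen gene Col1a2, 0.996 and 1.26 at Myh11, 2.71 and 3.09 at the lipid droplet gene Plin1 and 0.892 and 0.935 at Tal1.

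Lists for other organs, apart from gonadal steroidogenesis, were lower than the other genes. Hepatocyte genes had 2 of 12 with a promoter peak in both pools, as did kidney tubule and podocyte genes (adjusted p = 0.0080 for each, Fisher's exact test). Forebrain neuron genes had 2 of 11 (0.0126), spermatogenesis genes 1 of 10 (0.0080) and skeletal muscle genes 2 of 10 (0.0212, all by Fisher's exact test). The skeletal muscle call was lost with the 50% of peaks with the most signal (adjusted p = 0.0701), in replicate 2 alone (0.0658) and with promoters of 2 kb (0.0681, all by Fisher's exact test). Gonadal steroidogenesis genes had 5 of 10 (adjusted p = 0.572, Fisher's exact test), among them Cyp17a1, the gene of an enzyme of androgen synthesis, with 0.996 and 1.34, and Amh with 1.12 and 1.49. Hnf4a, Cdh16, Acta1, Rbfox3, Slc32a1, Prm1 and Prm2 had none in either pool, while Apoa2 had signals of 3.26 and 3.06 and Ckm 1.09 and 1.37. With promoters of 500 bp, 0 of 12 hepatocyte genes had a promoter peak in both pools, so Apoa2 was not among such genes.

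Every member of 4 further lists had a promoter peak in both pools. These were 12 housekeeping genes (adjusted p = 0.0137), 13 circadian clock genes (0.0101), 10 glucocorticoid response genes (0.0312) and 10 immediate early genes (0.0312, all by Fisher's exact test). The clock and glucocorticoid target gene Per1, which is in 2 of the lists, had signals of 15.9 and 17.4, the clock activator gene Arntl 10.6 and 11.6, Jun 15.4 and 16.9, Fos 3.67 and 4.67, and Dusp1, a phosphatase gene, 7.04 and 7.92. Gapdh had 6.2 and 7.63. Over all 21911 protein-coding genes, 13784 had a promoter peak in replicate 1, 14300 in replicate 2 and 13562 (61.9%) in both.

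**Figure D2:**
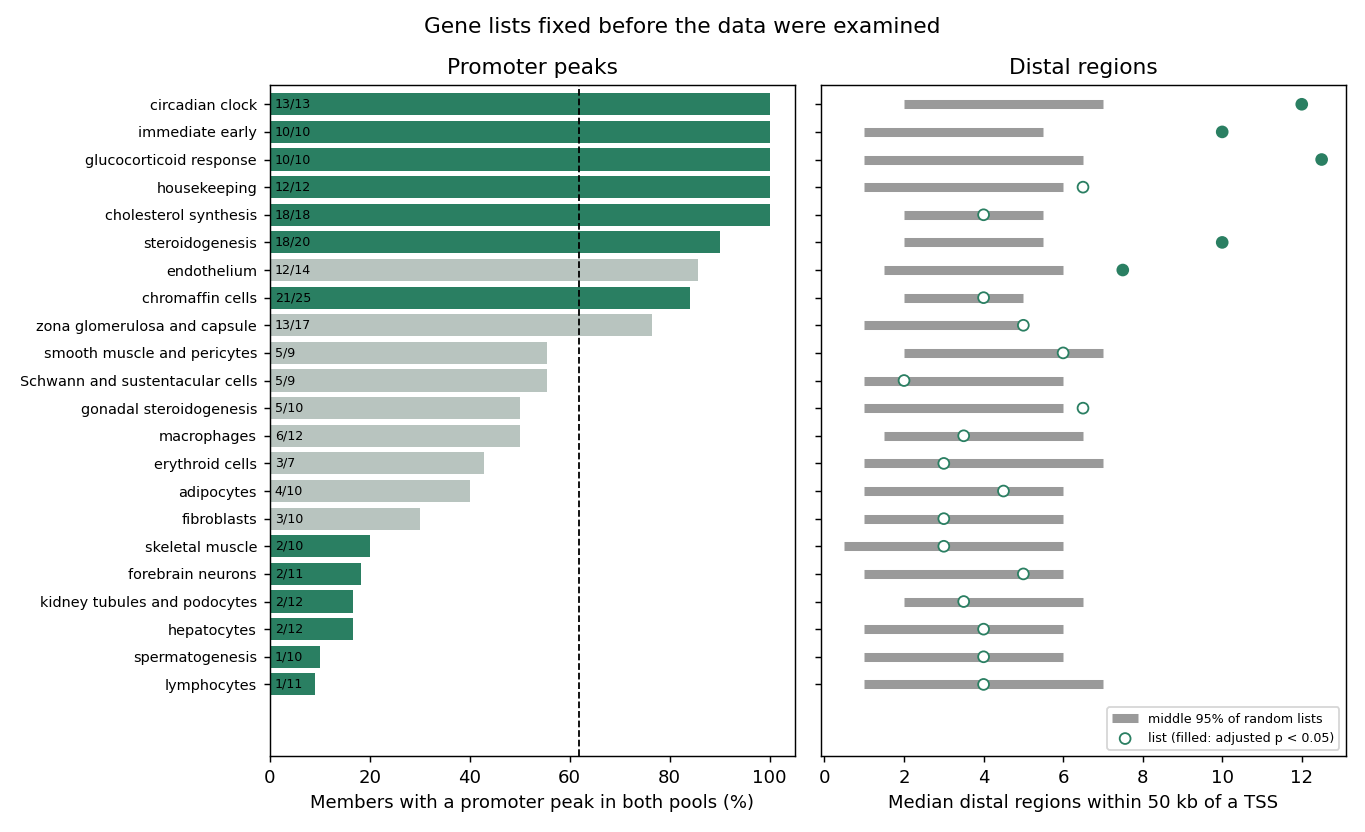
Left, percent of members of each gene list with a promoter peak in both pools, with counts in the bars, a dashed line at the 61.9% of all protein-coding genes, and dark bars where the adjusted p of Fisher's exact test was under 0.05. Right, the median number of shared distal regions within 50 kb per member (circles, filled where called) and the range of the middle 95% of matched random lists (grey), with glucocorticoid response at 12.5, circadian clock at 12 and steroidogenesis and immediate early at 10.

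Distal open regions were more numerous near steroidogenesis, glucocorticoid response, circadian clock and immediate early genes than near genes of matched random lists. Steroidogenesis genes had a median of 10 shared distal regions within 50 kb of a TSS, against 3.5 in matched random lists. Fdxr had 20, Hsd3b1, the gene of the 3β-hydroxysteroid dehydrogenase, 18, Star and Tspo 15 each and Cyp11a1 14. Glucocorticoid response genes had a median of 12.5 (random 3.5), with Per1 at 23 and Dusp1 at 20. Circadian clock genes had 12 (random 4), with Per1 again at 23 and Arntl at 17, and immediate early genes 10 (random 3), with Fos and Jun at 11 each. Each of these 4 lists had p = 0.0002, the smallest the permutations can give, and an adjusted p of 0.0011 in the permutation test. The random lists were matched on gene density and gene length, and not on promoter peaks. Whether genes with open promoters in general have more distal regions was therefore not tested.

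Endothelium genes had a median of 7.5 shared distal regions (random 3.5, adjusted p = 0.0264, permutation test), with Erg and Kdr at 9 each. That call did not hold with the shorter peak list (adjusted p = 0.317), with the 50% of peaks with the most signal (0.0851), in replicate 1 alone (0.0792) or with means in place of medians (0.196, all permutation tests). No list was lower. Medians of the other lists were 6.5 for gonadal steroidogenesis (adjusted p = 0.124) and housekeeping (0.109), 6 for smooth muscle and pericytes (0.636), 5 for zona glomerulosa and capsule (0.653) and forebrain neurons (0.803), and 4.5 for adipocytes (1, all permutation tests). They were 4 for cholesterol synthesis, chromaffin cells, lymphocytes, hepatocytes and spermatogenesis, 3.5 for macrophages and for kidney tubules and podocytes, 3 for fibroblasts, skeletal muscle and erythroid cells, and 2 for Schwann and sustentacular cells (adjusted p of 0.947 or 1 in the permutation test). Housekeeping genes passed in replicate 2 alone (adjusted p = 0.0183) and with means (0.00968), zona glomerulosa and capsule genes with means (0.0447), and gonadal steroidogenesis genes within 100 kb (0.00704, all permutation tests).

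Single members of lists that did not pass still had many neighbouring regions. Kcnk3 had 26, Znrf3 12, Dab2 11, and Axin2 and Cyp11b2 9 each. Fdft1 and Fdps had 10 each, Sc5d 7 and Dhcr7 6. Among chromaffin genes, Hand1 had 9, Chga 8, Snap25 and Th 7 each and Dbh 6. Gapdh, Fcer1g and Apoa2 had 13 each, Plin1, Amh and Cyp17a1 12 each, Cd4 and Cdh16 10 each, and Prm1 9. Fcer1g and Apoa2 lie next to each other on chromosome 1, as do Prm1 and Prm2 on chromosome 16, so each of these pairs shares regions. Over all genes the median was 4, and 3503 genes had none.

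Star lies on chromosome 8 on the plus strand, and its TSS in the annotation used is at 25808474. Within 50 kb of it there were 23 peaks and 82 footprints in replicate 1, and 27 peaks and 104 footprints in replicate 2. A peak at 25808281 to 25808540 covered the TSS with a signal of 5.44 and 6.52. The strongest peak was upstream, at 25806181 to 25806540 in replicate 1 (signal 8.57) and at 25806321 to 25806540 in replicate 2 (signal 7.77), with midpoints at -2114 and -2044 bp from the TSS. The annotated gene record, from 25806555 to 25815982, begins just beyond this peak.

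**Figure D3:**
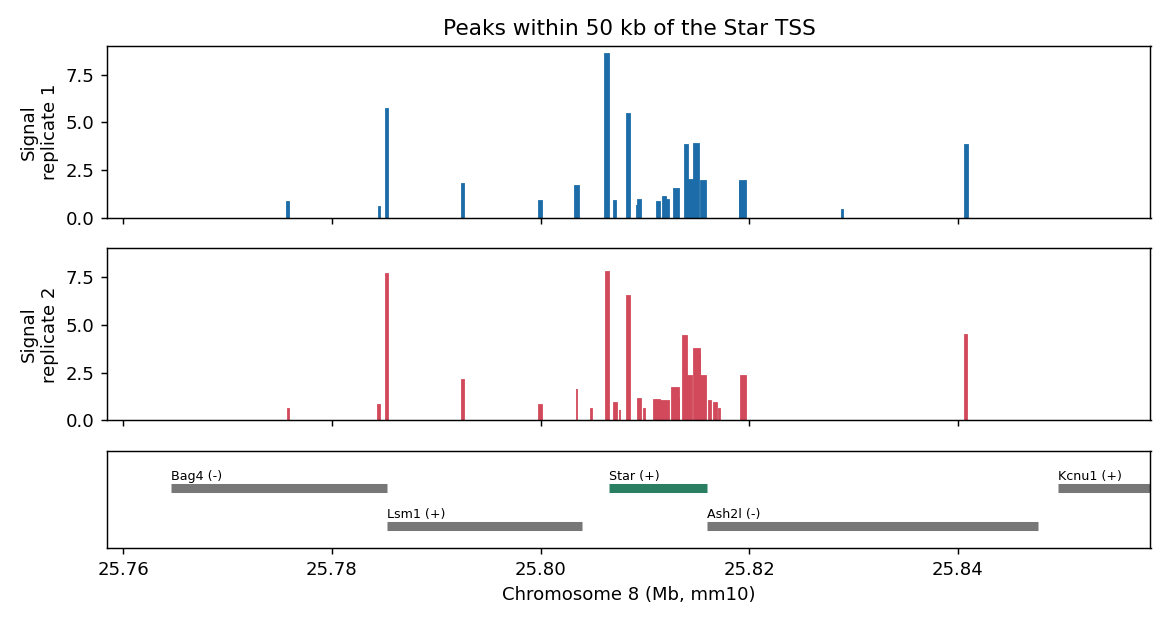
Peaks within 50 kb of the Star TSS in replicate 1 (top, blue) and replicate 2 (middle, red), drawn at their positions on chromosome 8 (Mb, mm10) with the authors' signal as height, above the protein-coding genes and their strands. The tallest peak, 8.57 and 7.77, lies upstream of the TSS peak, 5.44 and 6.52.

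Several motifs were more frequent in distal peaks than in flanking windows. No other tissue was compared, so whether these ratios are particular to the adrenal gland was not tested. The NR5A1 motif, which steroidogenic factor 1 binds, was found in 8.51% of 88051 distal peaks of replicate 1 and 8.36% of 113177 of replicate 2. These shares were 5.05 and 5.22 times those in flanking windows, but a match does not show which protein was bound. AP-1 motifs, bound by Fos and Jun dimers, were found in 16.8% and 17.3% of distal peaks (6.85 and 7.17 times the flanks), and CTCF motifs, which mark insulators, in 5.22% and 5.25% (7.24 and 7.50 times). The cAMP response element (CRE) was found in 0.532% and 0.435% of them (6.74 and 5.35 times), and NR4A motifs, bound by the immediate early nuclear receptors, in 2.42% and 2.5% (3.17 and 3.25 times). The glucocorticoid response element (GRE), which the mineralocorticoid, androgen and progesterone receptors also bind, was found in 1.12% of distal peaks in replicate 1 and 0.724% in replicate 2 (5.74 and 3.64 times the flanks, adjusted p = 8.06e-197 and 1.29e-109, Fisher's exact test).

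In all, 9 of 28 motifs were called, with NFI (11 and 18.2 times), MEF2 (1.74 and 1.73) and the E-box CAGCTG (2.02 and 2.00) beside these 6. Their adjusted p-values in Fisher's exact test were at most 3.59e-17 in replicate 1, for MEF2, and 2.9e-20 in replicate 2, also for MEF2, but peaks are not independent replicates. GATA motifs were in 7.92% and 7.89% of distal peaks, 1.29 and 1.26 times the flanks, which was under the ratio needed for a call, and they were called only against control windows of the same GC content. The E-box CAGCTG was not called with the shorter list, with the 50% of peaks with the most signal, with wider windows or over all peaks, MEF2 not with wider windows or over all peaks, and NFI not against windows of the same GC content. REST motifs, read by a repressor of neuronal genes, were 64.6 and 103 times as frequent as in the flanks, and NRF1 motifs 3.31 and 2.77 times, but neither could be called, because the reversed consensus had no match in the control windows. SP/KLF motifs (1.84 times in both pools) could not be called because their consensus is the same when reversed.

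**Figure D4:**
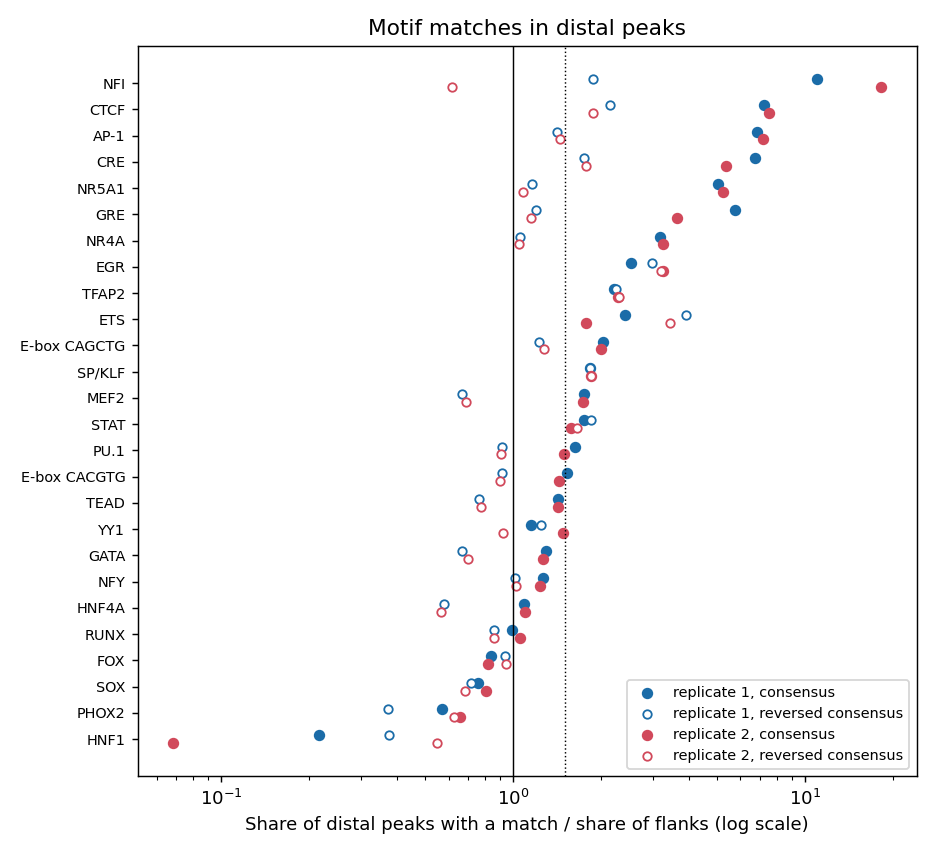
Share of distal peaks with a motif match divided by the share of flanking windows, on a log axis, for the 26 motifs whose reversed consensus had a match in the controls (filled, the consensus; open, the reversed consensus; blue, replicate 1; red, replicate 2). NFI (11 and 18.2), CTCF (7.24 and 7.50) and AP-1 (6.85 and 7.17) are farthest to the right, and the dotted line marks the ratio of 1.5 needed for a call.

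Footprints, short protected stretches inside open chromatin, numbered 272595 in replicate 1 and 319381 in replicate 2, with a median width of 9 bp. Of these, 90.6% and 89.5% lay in peaks, and 80.2% and 73.1% of peaks held at least one. CTCF motifs were 14.4 and 16.4 times as frequent in footprints as in other parts of the same peaks, CRE 15 and 12 times, NR5A1 3.82 and 4.43 times, and AP-1 3.31 and 4.37 times. NR4A (1.78 and 1.89 times), MEF2 (1.92 and 2.07), ETS (2.45 and 3.98), EGR (3.43 and 4.14), the E-box CACGTG (1.83 and 1.92) and NFI (78.0 and 47.0, from 1 and 2 control matches) were also called, 10 of 28 in all by the same rules as for distal peaks. SP/KLF motifs (5.57 and 6.67 times) again could not be called, nor could REST (6.67 and 26 times) and, in replicate 1, NRF1 (118.5 times, and 242 times in replicate 2), for lack of control matches of the reversed consensus. GATA motifs had ratios of 0.706 and 0.705. GRE motifs had 1.09 (adjusted p = 0.405) and 1.31 (adjusted p = 0.0103, both by Fisher's exact test) and were not called. Without the added bases MEF2 had ratios of 0.579 in replicate 1 and 1.25 in replicate 2 and GRE 0.529 and 0.55, none of which passed Fisher's exact test, and NFI had no control match.

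Between the pools, 51.1% of the footprints of replicate 1 and 42.6% of those of replicate 2 overlapped one of the other pool. In the regions shared by both pools, 54.6% of the 242492 footprints of replicate 1 overlapped one of replicate 2, and 49.6% of the 260297 of replicate 2 overlapped one of replicate 1. Footprints wholly inside these regions, placed at random in the same regions, overlapped in 30.7% and 28.6% of cases. The observed shares, which also count footprints that only touch a region, were 1.78 and 1.74 times these values. Random positions were uniform within a region and did not follow the density of cleavage. Peaks with a footprint had a median signal of 0.817 and 0.943, and peaks without one 0.409 and 0.344.

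Signal in the shared distal regions differed between the pools by motif, in a comparison chosen after the data were seen. Regions with a GRE had less signal in replicate 2 relative to all shared regions, with a centred median log2 ratio of -0.43 (bootstrap interval -0.47 to -0.40, 727 regions). Of these regions 88.2% lay below 0, and random regions of like signal and GC content had medians between -0.06 and 0.05. Medians were -0.13 for PU.1, the macrophage and lymphoid factor, -0.12 for CRE, -0.10 for SOX, -0.07 for GATA and -0.05 for NR5A1. Regions with CTCF motifs had a median of 0.13, those with AP-1 motifs 0.07, and those with NR4A motifs 0.04. In all, 11 of the 23 motifs measured lay outside the range of 1000 random sets, 7 below it and 4 above it. Within 50 kb of glucocorticoid response genes, 4 regions carried a GRE, and each lay below 0. They were 47259 bp from a TSS of Per1 (-0.86), 37186 and 29626 bp from one of Tsc22d3, the GILZ gene (-0.84 each), and 1063 bp from one of Mt2, next to Mt1 (-0.26). None is assigned to these genes. Centring subtracted 0.35 from each log2 ratio. Before centring, the region near Mt2 had more signal in replicate 2 than in replicate 1 (1.45 against 1.36), and the others had less.

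**Figure D5:**
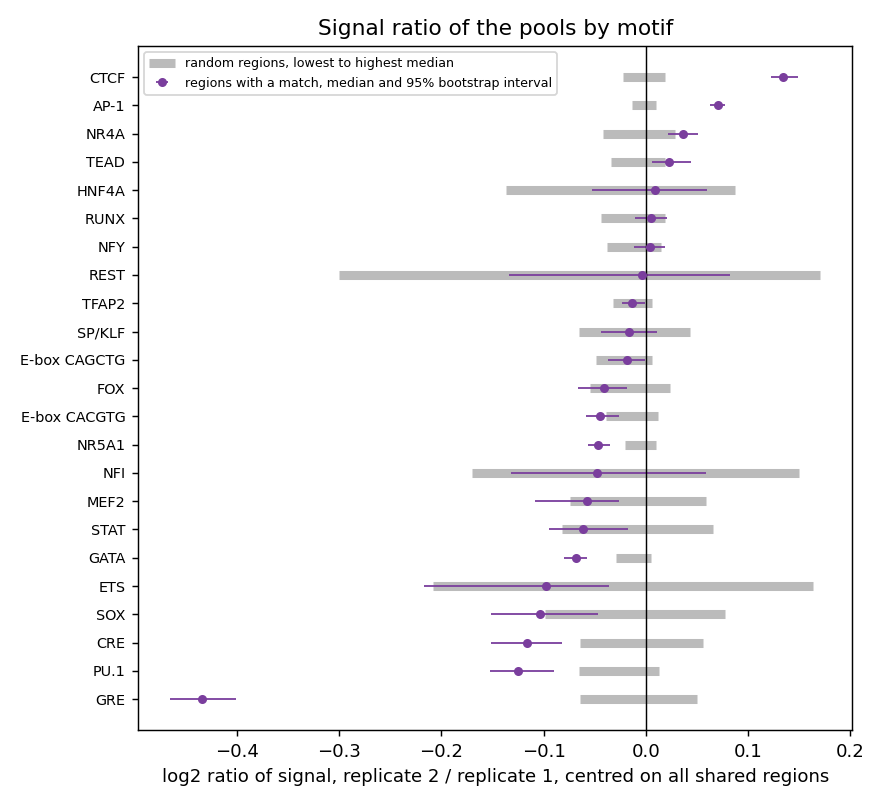
Median log2 ratio of signal, replicate 2 over replicate 1, centred on all shared regions (horizontal axis), in shared distal regions with each of 23 motifs, with 95% bootstrap intervals over regions (purple) and the range of medians of 1000 random sets matched on signal and GC content (grey). GRE stands apart at -0.43, and CTCF is highest at 0.13.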

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

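The alternatives for peaks by chromosome, other than each pool alone, were chosen only after the data were seen. Every other alternative was planned. The mean number of peaks was 82729 with the other peak list and 65919 with the 50% of peaks with the most signal, which keeps fewer peaks by construction. The share of peaks found in both pools, 76.2% on average, was 63.9% when 50% of both peaks had to overlap, and that of footprints went from 46.9% to 33.4%. Promoters held 28.9% of the other list's peaks, 32.2% of the 50% with the most signal and 17% of all peaks when limited to 500 bp. The X to autosome ratio of peak density, 0.425, was 0.388 with the other list, 0.236 with the 50% of peaks with the most signal and 0.363 with the same number of peaks in both pools. The cause of these shifts was not tested. With no bases added, MEF2 in footprints had a mean ratio of 0.914, from 0.579 in replicate 1 and 1.25 in replicate 2, so its direction changed in replicate 1 alone, neither ratio passed Fisher's exact test, and the cause was not tested.

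Taking 1 pool at a time gave 117371 to 146307 peaks, a promoter share of 22.6% to 25%, an X to autosome ratio of 0.417 to 0.433, 6 to 7 lists higher and 5 to 6 lower by promoter peaks, 4 to 6 lists higher and 0 lower by distal regions, 9 to 11 motifs called in distal peaks and 10 to 13 in footprints. Results on sharing between the pools have no such value. Of 154 values for single lists by promoter peaks, 140 kept their side of the threshold, 6 passed it newly and 8 no longer passed it. For lists by distal regions these numbers were 190, 4 and 4 of 198. In both tests some lists that were not called changed direction. Endothelium did so by promoter peaks with the other peak list, and hepatocytes by distal regions with the 50% of peaks with the most signal. Of 222 values for the 28 motifs in distal peaks, 204 kept their side of the threshold, 11 passed it newly and 7 no longer passed it. The new calls were TEAD with the 50% of peaks with the most signal, EGR, GATA and PHOX2 against windows of the same GC content, the E-box CACGTG, ETS, NFY, NRF1 and YY1 over all peaks, and the E-box CACGTG and PU.1 in replicate 1 alone. Of 77 values for 27 motifs in footprints, 73 kept their side of the threshold, and the others were MEF2 with no bases added and NRF1, PHOX2 and YY1, which were called in replicate 2 alone. GRE and TEAD, called in no footprint setting, had mean ratios under 1 with no bases added and over 1 in the main setting. Distal regions counted near 73 named genes moved in 314 of 511 cases. Between 7 and 12 motifs were called in distal peaks under the alternatives, and AP-1, CRE, CTCF, GRE, NR4A and NR5A1 were called in every one. A stricter set of footprints was not run, because all footprints carry the same value, and NFI, NRF1, PHOX2 and REST in footprints with no bases added, HNF1 in footprints in every setting and REST in distal peaks with the other list or the 50% of peaks with the most signal gave no value. The depth of the libraries is known only by inference, which leaves open how much of the weak peaks found in 1 pool is a matter of depth.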

Other observations

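The tests of the 3 patterns weighed here were written down before their own results were seen, but the GRE pattern was picked out because its share of distal peaks had been seen to differ between the pools, and the signal ratios by gene list were chosen only after the data were seen. Genes with many shared distal regions within 50 kb included Synpo, an actin-binding protein gene, with 35, Gramd1b, which encodes a carrier of cholesterol from the plasma membrane to the endoplasmic reticulum, with 31, and Ptgis, the prostacyclin synthase gene, with 31 and no promoter peak in either pool. Atp5d, Iqsec1 and Tmem107 had 29 each, and Cacna1c, the gene of a voltage-gated calcium channel, Cbarp and Mid1 had 28 each. Some of these are neighbours that share regions, such as Atp5d with Cbarp on chromosome 10, and Tmem107 with Per1 on chromosome 11.

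Relative to all shared regions, those within 50 kb of endothelium genes had less signal in replicate 2, with a median over genes of -0.15 and 14 of 14 genes below 0, a median lower than in all but 0.16% of random lists. Their promoter regions had -0.26 (percentile 0.21), with 10 of 12 below 0. Within 50 kb, Emcn had -0.45 and Tek, the angiopoietin receptor gene, -0.41. Macrophage genes had -0.15 (percentile 0.78), with 7 of 12 below 0, and their promoter regions had -0.64 (percentile 0.17), with 5 of 5 below 0, among them the mannose receptor gene Mrc1 at -0.91 and the complement genes C1qb at -0.64 and C1qa at -0.60. Regions near steroidogenesis genes had -0.07 (percentile 2.1), with 17 of 20 below 0, and their promoter regions -0.11 (percentile 0.5), with 14 of 18 below 0. Regions near glucocorticoid response genes had -0.11 (percentile 0.39), with 7 of 10 below 0, and their promoter regions -0.07 (percentile 9.95), with 6 of 10 below 0. Chromaffin promoter regions had 0.16 (percentile 84.7), with 16 of 21 above 0, among them Chga at 0.43 and Snap25 at 0.42, but regions within 50 kb of chromaffin genes had -0.01 (percentile 31.35), with 12 above and 13 below 0, Chga at -0.09 and Snap25 at 0.23. Of the 22 lists measured within 50 kb and the 11 with enough promoter regions, these are the ones named, chosen after their values were seen, and the values describe 2 libraries.

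Replicate 2 had more peaks although the total inferred from its signal step was lower, 125.1 against 134.6 in units of 1000000 cleavages, and 83.4% of shared regions had more signal in it before centring.

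Strong peaks found in 1 pool alone were few. Among the 10% of peaks with the most signal, 20 of replicate 1 and 59 of replicate 2 had no partner, among them those at Mrps18b (6.30), Manf (4.2) and AU040320 (3.89) and in an exon of the antisense gene Tbx3os1 (4.96) in replicate 1, and those at Esyt2 (7.36), Cand1 (6.79), Rpp38 (6.48) and Jkamp (6.31) in replicate 2. In the other pool, 100% of them held bases with an FDR under 0.05, against 26.9% and 12.2% of all unshared peaks. The border of the nearest peak of that pool lay a median of 150 and 160 bp from the midpoints of the strong peaks. The placement of peak borders in the other pool is therefore a possible explanation for the strong ones, while the weak ones stay open. No biological explanation was tested, since the design has 1 group.

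The lower density of peaks on the X chromosome had 2 candidate explanations, which do not exclude each other. If gene density were the whole cause, X genes would have promoter peaks as often as others, but 46.0% of 948 X genes had one in both pools (Wilson 95% interval 42.8% to 49.2%) against 63.1% of autosomal genes, a difference of -17.2 points. The gene density ratio, 0.669 (5.80 against 8.67 genes per Mb), was also above the ratio of peak densities, 0.417 and 0.433. Median promoter signal on the X was 0.601 times that of the autosomes in replicate 1 (bootstrap interval 0.533 to 0.647) and 0.560 times in replicate 2 (0.480 to 0.628), consistent with a single X copy per cell in males, which may put weak peaks under the threshold. No biological explanation such as the expression of X genes in this tissue was tested. The signal ratio cannot tell such an explanation from a single X copy.

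GRE matches made up a smaller share of distal peaks in replicate 2, with a ratio to replicate 1 of 0.648 (interval 0.590 to 0.710). The ratio was still 0.680 (0.617 to 0.75) with the same number of best peaks in both pools. A larger number of weak peaks in replicate 2 was therefore not enough to account for the smaller share. The intervals of both ratios treat peaks as independent samples, although the pools share most peaks, and do not measure spread between pools. Regions with the reversed motif moved by 3.14% of the signal shift of GRE regions (interval -9.73% to 22.3%, 159 regions), which argues against base composition as the whole cause. Those with an NR5A1 motif and no GRE moved by 9.99% of it (7.31% to 12.6%, 6580 regions). This fraction cannot decide whether a smaller share of cortical steroid-producing cells was the cause, because centring removes a shift common to most regions. The cells in which the NR5A1 regions are open are also not known. All regions with an NR5A1 motif had a median of -0.05, below the random sets (-0.02 to 0.01), and steroidogenesis promoters moved further, at -0.11. A hypothesis is that glucocorticoid receptor activity, or that of another steroid receptor with this motif, may have differed between the pools, which receptor binding or hormone levels measured in the same glands would decide, but no hormone level, time of day or handling was given in the sources used here and no biological explanation was tested. Differences in cell make-up, such as the endothelial and macrophage genes above or a part played by cortical cells, also stay open.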
